A study of Mus musculus with 11 samples.

How the data were processed

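RNA was measured on Affymetrix whole-transcript arrays in pools of 40 late 2-cell mouse embryos, 1 pool per array. The labels put 11 arrays into 4 groups. Control embryos came from eggs without Ring1 but with Rnf2, and mutant embryos from eggs without Ring1 and Rnf2, the pair of E3 ligase subunits of Polycomb repressive complex 1 (PRC1). Each genotype was left untreated (3 control and 3 mutant arrays) or cultured with α-amanitin, an inhibitor of RNA polymerase II, at 24 µg/ml from 6 h after fertilization until harvest at 35 h (3 control and 2 mutant arrays). All eggs were fertilized in vitro with wild-type sperm, the background was a mix of 129/Sv and C57BL/6J, and embryos of several mice were pooled, per the labels' protocols. The RNA was amplified by whole-transcriptome amplification before labelling. Replicates are described in the labels as biological replicates, and the number of arrays limits the precision. The labels name no batch, and the harvest time of the untreated embryos is not given in the sources used here.

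The deposited values are on a log2 scale, as their range from 1.11 to 12.8 shows. R 2.10.0 and the affy package were used, per the submitters' processing notes. The background correction and the normalization between arrays are not given in the sources used here. No spike-in was used here, so each value is relative to the other RNA on its array. An equal change of all RNA would not be seen. The array medians lay between 4.45 and 4.55, and the 75th percentiles between 4.93 and 5.28. No values below the background were marked, so a probe set near the array median has little room to fall.

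The value table held 34760 probe sets. The platform annotation gave 1 gene symbol to 22878 of them, several to 1734 and none to 10148, including 31 that it did not list, and it marked 0 as controls. Probe sets with several symbols were tested but never named. Old symbols were updated through Entrez identifiers: 19629 probe sets had an identifier found in the reference gene table and 239 had one that was not found, while 3010 with 1 gene had none. The update changed 3073 symbols, left 16121 that were already current and kept 435 without a match. No coordinates are given, because the genome build is not stated in the sources used here. For genes and gene lists, the probe set with the highest mean over the 11 arrays stood for the gene, which gave 21231 genes.

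The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 11 arrays, then eBayes), with no filter on dim probe sets. The fit had 7 residual and 3.59 prior degrees of freedom. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 34760 probe sets, and an adjusted p below 0.05 counted as a change. Fits gave 5 comparisons: mutant minus control without and with α-amanitin, untreated minus α-amanitin in control and in mutant embryos, and the interaction, which is the untreated minus α-amanitin difference in mutant minus that in control embryos. Values written with ± are log2 differences with limma's standard error.

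Altogether 27 gene lists were tested in each comparison: PRC1 subunits, PRC2 subunits, Hox genes, developmental regulators known as Polycomb targets, germline genes, 2-cell activation genes, ribosome biogenesis, splicing factors, proteasome subunits, translation factors, cytosolic ribosomal proteins, oocyte and maternal-effect genes, pluripotency and first-lineage regulators, mitotic genes, DNA replication genes, CDK inhibitors and D cyclins, p53 targets, DNA methylation factors, trithorax and demethylase genes, imprinted genes, chaperones, the unfolded protein response, glycolysis, the respiratory chain, signalling ligands and receptors, cumulus and granulosa markers, and sperm markers. The camera test asked whether a list moved more in 1 direction than the other genes, with a preset correlation of 0.01 between genes and, as an alternative, with a correlation estimated from the residuals. Its p-values were adjusted over the lists of a comparison. With the estimated correlation, the only list call that held in any comparison was that of the 2-cell activation genes for α-amanitin treatment in mutant embryos.

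The groups, the tests, the gene lists, the alternatives and the genes to be named were chosen before the data were examined. The rule for naming took genes past the threshold whose groups did not overlap (no such condition for the interaction) and passed over clone names. It took the 10 largest rises and falls for both genotype comparisons and for treatment in control embryos, the 5 largest for treatment in mutant embryos and for the interaction, up to 4 members of each list with the smallest adjusted p, and all PRC1 subunits. Genes outside the rule are said to have been chosen after their values were seen. Counts over the list alone adjust p over the members only. Where several probe sets represent a gene, the number called the same way is given if they differ, and such genes are uncertain.

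Rnf2 and Ring1 were also compared with an exact permutation test. Correlations across probe sets and overlaps of calls have no p-value, since probe sets are not independent replicates. The untreated genotype comparison and the treatment comparison in control embryos share the untreated control arrays, and unchanged groups against shared arrays were simulated 100 times for the correlation and 20 times for the overlap.

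The fit was tested on simulated data of 34760 probe sets with 200 of them changed by known amounts. For untreated mutant against control, it recovered 26.9% of changes of 0.5, 80.6% of 1 and 97.0% of 2 on the log2 scale. The recovered shares with α-amanitin were 20.9%, 83.6% and 95.5%. For treatment, they were 41.8%, 85.1% and 97.0% in control and 20.9%, 65.7% and 97.0% in mutant embryos, and for the interaction 2.99%, 62.7% and 95.5%. False calls numbered 1, 5, 8, 5 and 3 in the same order.

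Alternatives were median centring, quantile and cyclic loess normalization, the brighter 50% of probe sets, 1 probe set per gene, the mean of a gene's probe sets, array weights, an intensity trend with a robust prior, only the arrays of the groups compared, an adjusted p below 0.01, a change of at least 2-fold, the replicate number as a block, each array left out in turn and, chosen after seeing the data, probe sets with a gene symbol only.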

Results

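Expression was measured in 11 arrays, each of a pool of 40 late 2-cell embryos, in 4 groups: 3 untreated control, 3 untreated mutant, 3 α-amanitin-treated control and 2 α-amanitin-treated mutant pools. Control embryos lacked maternal Ring1 and mutant embryos lacked maternal Ring1 and Rnf2, so the genotypes differ in maternal Rnf2. α-amanitin blocks transcription, so treated embryos should hold mainly RNA inherited from the egg. Replicates correlated at 0.966 to 0.984 within a group. Untreated control and treated control arrays correlated at 0.805 to 0.822, untreated mutant and treated mutant arrays at 0.928 to 0.949, and untreated control and mutant arrays at 0.889 to 0.933. The first principal component held 62.0% of the variance and ran from the untreated control arrays, at 71.0 to 80.5, over the untreated mutant arrays, at -8.50 to 12.1, to the treated arrays, which lay between -54.9 and -32.5. Treated mutant replicate 2 had a wider distribution than replicate 1, with 14.2% against 11.0% of probe sets above a log2 value of 6. This share was 11.2% to 12.6% in treated control, 11.9% to 12.9% in untreated mutant and 15.1% to 16.1% in untreated control arrays.

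Rnf2, the gene that separates the genotypes, was read by probe set 10358698. Its log2 values were 6.84, 6.59 and 6.70 in untreated control, 5.00, 5.17 and 5.08 in untreated mutant, 7.31, 6.89 and 7.02 in treated control, and 5.18 and 5.24 in treated mutant arrays. The difference was -1.63 ± 0.11 without α-amanitin (limma's adjusted p = 7.97e-06) and -1.86 ± 0.13 with it (adjusted p = 2.99e-05). Every mutant array lay below every control array, and the exact permutation p was 0.1 in both, the smallest these designs allow. Ring1, absent from the eggs of both genotypes by the labels, lay between 4.35 and 4.79 in all arrays. Its genotype difference was -0.07 untreated (exact permutation p = 0.7) and -0.11 with α-amanitin (exact permutation p = 0.2). Whether either probe set lies inside the deleted part of its gene is not given in the sources used here, so the Ring1 values check nothing, while the Rnf2 values separate the genotypes as labelled.

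**Figure D1:**
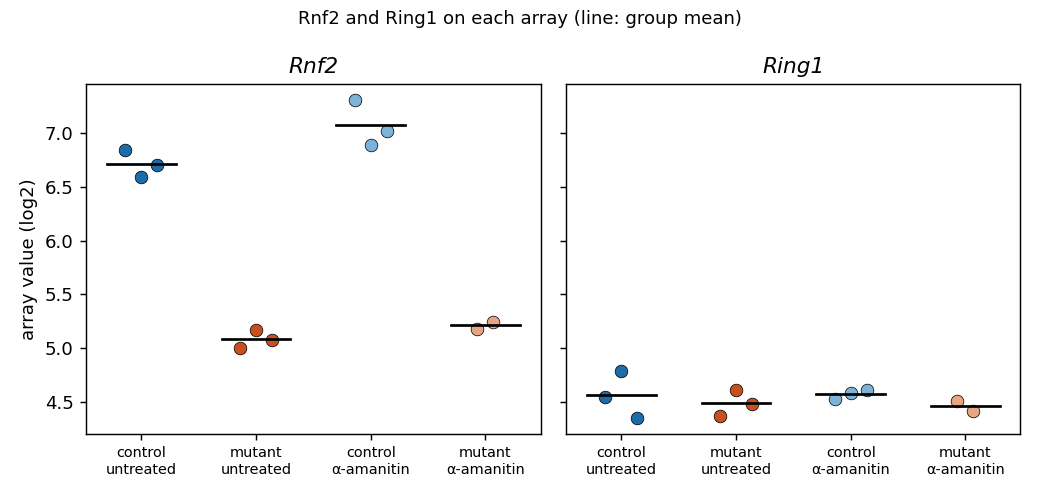
Log2 expression of Rnf2 and Ring1 in each of the 11 arrays (dots) with the group means (lines), for untreated and α-amanitin-treated control and mutant embryos. Rnf2 lies between 5.00 and 5.24 in the 5 mutant arrays and between 6.59 and 7.31 in the 6 control arrays, and Ring1 lies between 4.35 and 4.79 in all.

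The comparison of untreated embryos asked how the 2-cell transcriptome differs when the egg lacks Rnf2 as well as Ring1. Mutant embryos held less RNA for making ribosomes: 67 of 70 ribosome biogenesis genes and 53 of 63 cytosolic ribosomal protein genes fell. Splicing factors, translation factors, proteasome subunits and mitotic genes also fell in most cases. Oocyte and maternal-effect genes went the other way, with 24 of 56 higher in the mutant, and 7 of 38 Hox genes, the homeobox genes that pattern the body axis, rose while none fell. Altogether 7117 probe sets changed, 2365 up and 4752 down in the mutant (33.2% up), and after quantile normalization 3993 rose and 3629 fell (52.4% up). At least 2-fold changes numbered 327 up and 1726 down. The 3 mutant arrays did not overlap the 3 control arrays in 12159 probe sets, where chance gives 10%.

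Among single genes, the largest rise was that of Gm4340 (2.83 ± 0.19), followed by Eola1 (2.43 ± 0.16, adjusted p = 7.14e-06, a 5.40-fold difference, n = 3 and 3). Ly6e, a membrane-anchored surface protein, rose by 2.39 ± 0.10, and Psenen, a subunit of the gamma-secretase complex, by 2.38 ± 0.14. Mt4, a metallothionein, rose by 2.20 ± 0.18, Plac1, an X-linked gene expressed in trophoblast, by 2.16 ± 0.13, Rgs2, a regulator of G protein signalling, by 2.11 ± 0.15, and Tubb3, a beta-tubulin, by 2.01 ± 0.13. Ddah1 (1.98 ± 0.17), the chemokine receptor gene Cxcr3 (1.98 ± 0.17) and the proton pump gene Atp6v1f (1.92 ± 0.18) came next. The largest falls were those of H2-Q6, a class I histocompatibility gene (-2.91 ± 0.24, adjusted p = 1.72e-05), the lysosomal protease Ctsc (-2.84 ± 0.35), Npl (-2.80 ± 0.25), the cytochrome oxidase copper chaperone Cox17 (-2.79 ± 0.18), Flvcr2 (-2.78 ± 0.19) and Tomm5, part of the mitochondrial import pore (-2.78 ± 0.22). Rps25 (-2.66 ± 0.29) and Rps18 (-2.61 ± 0.26), of the small ribosomal subunit, are uncertain, since 4 of 6 and 3 of 4 of their probe sets were called.

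With an estimated correlation none of the 14 lists called for this comparison passed (adjusted p = 0.554 to 0.612). Ribosome biogenesis genes had a median of -1.24, and 70 of 70 fell when over the list alone (camera adjusted p = 5.5e-34). Bop1 and Pno1, which process ribosomal RNA precursors, fell by 1.63 ± 0.10 and 1.56 ± 0.09, and Tbl3 fell by 1.82 ± 0.12. Ribosomal proteins had a median of -1.37, with 54 falling and 1 rising over the list alone (camera adjusted p = 2.48e-23). Rps27 fell by 1.84 ± 0.17. Of 59 splicing factors, 36 fell and none rose (44 fell and 2 rose over the list alone), with a median of -0.59 (adjusted p = 2.46e-12), among them Srsf1 (-1.41 ± 0.12) and Hnrnpm (-1.47 ± 0.13). Of 48 translation factors, 33 fell and 1 rose (37 and 2 over the list alone), median -0.89 (adjusted p = 9.81e-14). Eif3a and Eif3g, subunits of the initiation factor that binds the small ribosomal subunit, fell by 1.86 ± 0.14 and 1.86 ± 0.12. Of 40 proteasome subunits, 23 fell and 2 rose (27 and 3 over the list alone), median -0.60 (adjusted p = 1.55e-07). Psmb5, a catalytic subunit, fell by 2.42 ± 0.23.

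Mitotic genes fell in 33 and rose in 5 of 53 cases (35 and 8 over the list alone), median -0.77 (adjusted p = 2.5e-07). The spindle motor gene Kif11 fell by 1.36 ± 0.13 and Cdca8, of the chromosomal passenger complex, by 1.42 ± 0.15, while the phosphatase gene Cdc25b rose by 1.06 ± 0.11. DNA replication genes fell in 19 and rose in 4 of 52 cases (22 and 5 over the list alone), median -0.22 (adjusted p = 0.000484). Gins3 and Cdc45, parts of the replicative helicase, fell by 2.39 ± 0.18 and 1.40 ± 0.12. The chaperone list had 17 falls and 3 rises among 29 (20 and 3 over the list alone), median -0.59 (adjusted p = 2.43e-05). The chaperonin subunit Cct4 fell by 1.43 ± 0.12. The respiratory chain list had 35 falls and 11 rises among 66 (37 and 15 over the list alone), median -0.42 (adjusted p = 0.000484). Cox7c fell by 2.0 ± 0.16. The unfolded protein response list had 14 falls and 3 rises among 27 (15 and 3 over the list alone), median -0.42 (adjusted p = 0.0011). Ppp1r15b fell by 1.45 ± 0.14. Trithorax and demethylase genes fell in 9 and rose in 1 of 25 cases (9 and 1 over the list alone), median -0.17 (adjusted p = 0.0249), and this median was 0.15 after quantile normalization. Kdm5b, an H3K4 demethylase, fell by 1.85 ± 0.19 and the chromatin remodeller Chd1 by 1.21 ± 0.08. Quantile normalization ended the calls of the replication (adjusted p = 0.377), trithorax (0.998), chaperone (0.0555), unfolded protein response (0.152) and respiratory chain (0.233) lists. The brighter 50% of probe sets ended those of replication (0.0723), trithorax (0.278) and respiratory chain (0.0893), and the trithorax call also ended with cyclic loess (0.13) and without untreated control replicate 1 (0.0595). Quantile normalization also gave smaller medians for splicing (-0.28), proteasome (-0.21), translation (-0.56) and mitotic genes (-0.43), which kept their calls.

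Oocyte and maternal-effect genes rose in 24 and fell in 2 of 56 cases (26 and 3 over the list alone), median 0.33, or 0.76 after quantile normalization (adjusted p = 3.06e-09). The oocyte transcription factor gene Sohlh2 rose by 1.36 ± 0.10, Pabpc1l, the poly(A)-binding protein of oocytes, by 1.31 ± 0.09, Tcl1 by 1.82 ± 0.14 and the homeobox gene Obox5 by 1.51 ± 0.14. Of the 38 Hox genes, 12 rose and none fell over the list alone, median 0.17, or 0.27 over the brighter 50% of probe sets (adjusted p = 3.08e-05). Hoxd8 rose by 1.08 ± 0.14 and Hoxd9 by 0.66 ± 0.09. The developmental regulators known as Polycomb targets rose in 14 and fell in 3 of 89 cases, the same counts over the list alone, median 0.09 (adjusted p = 0.000658). Otx1 and En2, which pattern the brain, rose by 0.77 ± 0.09 and 0.64 ± 0.08. Pax6 (0.89 ± 0.12) is uncertain, since 1 of its 2 probe sets was called.

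The PRC1 list had 4 rises and 4 falls among 22 genes (5 and 4 over the list alone, adjusted p = 0.776), and its median of 0.01, which is -0.02 after median centring, and camera's upward direction differ in sign from its mean of -0.09. Besides Rnf2, the alternative PRC1 subunits Pcgf5 (-1.36 ± 0.16) and L3mbtl2 (-1.28 ± 0.19) fell, while Kdm2b, which recruits PRC1 to CpG islands, rose by 0.76 ± 0.17, Scmh1 by 0.72 ± 0.15 and Phc1 by 0.68 ± 0.15. Pcgf6 fell by 0.63, a call lost with quantile normalization (-0.21) and without untreated control replicate 3 (-0.60) or untreated mutant replicate 2 (-0.55). Cbx2 rose by 0.37, a call lost with median centring (0.34) or the trend prior (0.37), without untreated control replicate 2 (0.31) or 3 (0.33), without untreated mutant replicate 1 (0.34) or 2 (0.32), and without any of the 3 treated control arrays (0.37). Of 11 PRC2 genes 6 fell and 2 rose (7 and 2 over the list alone), median -0.47 (adjusted p = 0.0719). The accessory subunit Mtf2 fell by 1.63 ± 0.17 and the core subunit Suz12 by 0.80 ± 0.11. The PRC2 list passed without untreated control replicate 2 (0.0368), without untreated mutant replicate 1 (0.0372), without either treated mutant array (0.0392 each) or with only the groups compared (0.042), and its median was -0.02 after quantile normalization.

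The 2-cell activation genes, a set transcribed as the embryonic genome starts up, rose in 7 and fell in 13 of 36 cases (8 and 17 over the list alone), with a median of -0.30 that was 0.05 after quantile normalization (adjusted p = 0.081). Gm4340 rose and Obox6 and Pramel6 fell by 1.77 ± 0.17 and 1.60 ± 0.11. Pluripotency and first-lineage regulators had 9 rises and 12 falls among 40 (12 and 13 over the list alone, adjusted p = 0.988), a median of 0.00 (-0.02 after median centring), a mean of -0.10 and an upward camera direction. Pou5f1, the core pluripotency factor Oct4, rose by 1.37 ± 0.13, and Dppa4 and Esrrb fell by 1.64 ± 0.17 and 0.78 ± 0.08. DNA methylation factors had 4 rises and 9 falls among 31 (4 and 10 over the list alone, adjusted p = 0.081), median -0.18, or 0.02 after quantile normalization. The DNA demethylase gene Tet1 fell by 1.76 ± 0.11 and Dnmt3l, a cofactor of de novo methylation, rose by 1.08 ± 0.10. Imprinted genes rose in 6 and fell in 6 of 34 cases (9 and 6 over the list alone, adjusted p = 0.172, median 0.07). The growth factor gene Igf2 rose by 1.75 ± 0.13 and its clearance receptor gene Igf2r fell by 1.73 ± 0.11. Germline genes rose in 8 and fell in 4 of 36 cases (10 and 4 over the list alone, adjusted p = 0.253, median 0.08) and passed after quantile normalization (0.0344). Tuba3a rose by 1.29 ± 0.13. Glycolysis had 5 rises and 5 falls among 22 (6 and 6 over the list alone, adjusted p = 0.997) with a mean of 0.01 and a median of -0.01, which was 0.04 after quantile and 0.01 after cyclic loess normalization, and camera's direction was downward.

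Targets of p53 rose in 5 and fell in 13 of 33 cases (5 and 13 over the list alone, adjusted p = 0.177, median -0.08). Sesn2 fell by 2.1 ± 0.16. Signalling ligands and receptors rose in 7 and fell in 6 of 58 cases, with the same counts over the list alone (adjusted p = 0.598), a median of 0.02 (-0.01 after median centring), a mean of -0.03 and an upward camera direction. Fgf4, a growth factor of the early embryo, fell by 1.13 ± 0.13. CDK inhibitors and D cyclins had 2 rises and 3 falls among 15, the same over the list alone (adjusted p = 0.654), a median of 0.03, a mean of -0.001 and an upward camera direction, with Ccnd2 at 0.91 ± 0.15, Cdk4 at -1.27 and Cdkn2d at -0.91 ± 0.08. Cumulus and granulosa markers, of the cells that surround the egg, had 3 rises and 1 fall among 30, the same over the list alone (adjusted p = 0.081, median 0.07). Ptgs2 rose by 1.30 ± 0.15 and Amhr2 fell by 1.68 ± 0.12. Sperm markers had 1 rise, Prm2 at 0.61 ± 0.14, and 1 fall, Ldhc at -0.62 ± 0.10, among 20, the same over the list alone (adjusted p = 0.285), with a median of 0.03 that was -0.01 after quantile normalization. Without untreated mutant replicate 1, the 2-cell (0.00697), DNA methylation (0.0317) and cumulus (0.0357) lists passed.

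Several members moved against their list, and those named here were chosen after their values were seen. The rises were Rpl27a (0.59) among ribosomal proteins, Eef1b2 (0.44) among translation factors, Psmd10 (1.05) and Psmb3 (0.45) among proteasome subunits, Wee2 (1.07), Nuf2 (1.02), Pttg1 (1.01) and Ccnb2 (0.32) among mitotic genes, and Rfc3 (0.91), Lig1 (0.58), Rpa3 (0.42) and Orc5 (0.37) among replication genes. Dnajb4 (0.77), Hspe1 (0.62) and Hsf2 (0.55) rose in the chaperone list, Ddit3 (0.56), Atf3 (0.53) and Asns (0.25) in the unfolded protein response list, Plk2, Perp, Gadd45g, Btg2 and Pmaip1 among p53 targets, and Rbbp7 (0.37) and Phf19 (0.34) in PRC2. The falls were Gpr3 (-1.0) and Zp3 (-0.51) among oocyte genes, Tbx3 (-0.52), Gata4 (-0.36) and Neurog2 (-0.27) among developmental regulators, and Rpl10l, Piwil2, Mov10l1 and Tex101 among germline genes.

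With α-amanitin, the genotype comparison is over RNA inherited from the egg as far as the block was complete. Here the housekeeping lists that were lower in the untreated mutant were higher in the mutant: 31 of 66 respiratory chain genes, 20 of 40 proteasome subunits and 20 of 63 ribosomal protein genes rose, and 0, 2 and 0 of them fell. Mitotic genes rose in 27 of 53 cases and splicing factors in 22 of 59. Among PRC1 genes, Kdm2b rose by 2.01 ± 0.19 and Bcor by 1.17 ± 0.14 while Rnf2 fell. In all, 3144 probe sets changed, 1920 up and 1224 down (61.1% up), and after quantile normalization 2227 rose and 2322 fell (49.0% up). Without treated mutant replicate 1, 2437 rose and 596 fell, and without replicate 2, which has the wider distribution, 1021 rose and 1388 fell. Array weights gave 2050 changed probe sets, and only the groups compared gave 1231. The treated groups did not overlap in 10366 probe sets, where chance gives 20% for 3 against 2 arrays.

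Snrpd3, a core protein of the spliceosomal snRNPs, rose most (3.06 ± 0.15, adjusted p = 7.32e-06, 8.34-fold, n = 3 and 2). Mt1, a metallothionein, rose by 3.03 ± 0.11, the retinoic acid-binding protein gene Crabp2 by 2.96 ± 0.38, Magoh, of the exon junction complex, by 2.66 ± 0.14, and Uqcrh, of respiratory complex III, by 2.63 ± 0.24. Plac1 (2.67 ± 0.14), Rgs2 (2.48 ± 0.17), Tubb3 (2.47 ± 0.15) and Ddah1 (2.47 ± 0.19) were among the largest rises here too. Defa29 (2.54 ± 0.23) is uncertain, with 1 of 2 probe sets called. Among named genes, Tnfaip8 (-2.01 ± 0.17), the cysteine dioxygenase gene Cdo1 (-1.98 ± 0.18), Rnf2, Zfp932 (-1.76 ± 0.29), the histone gene H2bc1 (-1.73 ± 0.17), the prolactin receptor gene Prlr (-1.57 ± 0.17), the cell cycle regulator E2f4 (-1.56 ± 0.15), Pkn2 (-1.50 ± 0.18) and Adm2 (-1.49 ± 0.17) fell most. Scoc (-1.57 ± 0.25) was called in 1 of its 2 probe sets.

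With an estimated correlation none of the 12 lists called for this comparison passed (adjusted p = 0.589 to 0.796). The respiratory chain list had a median of 0.49, with 35 rises and 1 fall over the list alone (camera adjusted p = 5.91e-15). Ndufa1, of complex I, rose by 2.42 ± 0.18, and Cox6c and Cox6b1, of complex IV, by 2.37 ± 0.20 and 2.04 ± 0.17. Splicing factors had a median of 0.45, with 22 rises and 1 fall (34 and 2 over the list alone, camera adjusted p = 4.94e-14), among them Snrpf (2.35 ± 0.14). Proteasome subunits had a median of 0.69 (26 rises and 2 falls over the list alone, camera adjusted p = 9.97e-12). Psmb3 rose by 2.34 ± 0.15 and Psmb6 by 1.94 ± 0.18. Mitotic genes had a median of 0.53, with 27 rises and 4 falls (32 and 6 over the list alone, camera adjusted p = 2.57e-11). Pttg1, the securin gene, rose by 2.22 ± 0.16, the kinase gene Aurka by 2.06 ± 0.21 and Ccnb1, the M-phase cyclin gene, by 1.63 ± 0.14. Ribosome biogenesis rose in 20 and fell in 1 of 70 cases (36 and 1 over the list alone), median 0.41 (adjusted p = 7.52e-11). Nop56 rose by 1.91 ± 0.25 and Npm1 by 1.55 ± 0.16. Ribosomal proteins had a median of 0.48 (27 rises and no falls over the list alone, adjusted p = 2.73e-10). Rplp1 rose by 2.35 ± 0.19 and Rps29 by 1.67 ± 0.18. DNA replication genes rose in 18 and fell in 3 of 52 cases (22 and 5 over the list alone), median 0.36 (adjusted p = 1.21e-05). Mcm7, of the replicative helicase, rose by 1.41 ± 0.16 and Cdc45 by 1.34 ± 0.13.

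Glycolysis rose in 6 and fell in none of 22 cases (9 and 1 over the list alone), median 0.25 (adjusted p = 0.0014). Gapdh rose by 1.31 ± 0.16 and Ldha by 1.13 ± 0.12. Chaperones rose in 9 and fell in 1 of 29 cases (12 and 3 over the list alone), median 0.38 (adjusted p = 0.00057). Hspb1 rose by 2.31 ± 0.21 and Cct8 by 1.35 ± 0.10. Translation factors rose in 12 and fell in 4 of 48 cases (18 and 4 over the list alone), median 0.30 (adjusted p = 0.00194). Eef1b2 rose by 1.81 ± 0.16 and Eif4a1 by 1.36 ± 0.15. Oocyte and maternal-effect genes rose in 16 and fell in 5 of 56 cases (18 and 10 over the list alone), median 0.16 (adjusted p = 0.0195). Dppa3, a maternal protector of DNA methylation, rose by 2.46 ± 0.14, Sohlh2 by 1.62 ± 0.11 and Pabpc1l by 1.04 ± 0.10. Germline genes rose in 7 and fell in none of 36 cases (8 and none over the list alone), median 0.12 (adjusted p = 0.0323). The meiotic axis gene Sycp3 rose by 1.89 ± 0.21 and Tex19.1 by 1.78 ± 0.15. Without treated mutant replicate 2 the germline (adjusted p = 0.116), translation (0.322), oocyte (0.736, median -0.08) and chaperone (0.0738) calls were lost. The medians without it were 0.29 for ribosomal proteins, 0.24 for ribosome biogenesis, 0.25 for splicing, 0.34 for mitosis, 0.19 for replication and 0.11 for glycolysis, which kept their calls. Without replicate 1 the medians were 0.54 for translation, 0.61 for chaperones, 0.46 for glycolysis, 0.33 for oocyte and 0.26 for germline genes. The germline call was also lost with quantile (0.0605) and cyclic loess (0.0551) normalization and over the brighter 50% of probe sets (0.113). The oocyte call was lost over the brighter 50% (0.119), without treated control replicate 2 (0.128) or with only the groups compared (0.0583), and its median was 0.28 after cyclic loess. The chaperone median was 0.16 with the mean of a gene's probe sets.

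In the PRC1 list 4 genes rose and 2 fell (4 and 3 over the list alone, adjusted p = 0.895), median 0.02, or -0.01 after median centring or quantile normalization. Bcorl1 rose by 0.83 ± 0.13. Cbx8 rose by 0.54, a call lost without treated mutant replicate 2 (0.44), and Bmi1 fell by 0.70 ± 0.14, a call lost without treated mutant replicate 1 (-0.68) or 2 (-0.72). PRC2 had 3 rises and 1 fall among 11 (3 and 3 over the list alone, adjusted p = 0.59), median 0.22, or 0.13 and 0.03 without treated mutant replicates 1 and 2. Rbbp7 rose by 1.38 ± 0.13, Rbbp4 by 1.18 ± 0.13 and Suz12 fell by 1.09 ± 0.12. Jarid2 (0.56) was not called with only the groups compared. Hox genes rose in 5 and fell in none of 38 cases (6 and none over the list alone, adjusted p = 0.194, median 0.04). Hoxd8 rose by 0.99 ± 0.15 and Hoxd9 by 0.78 ± 0.10. Developmental regulators rose in 11 and fell in 1 of 89 cases (13 and 1 over the list alone, adjusted p = 0.101, median 0.04). En2 rose by 0.76 ± 0.09. Imprinted genes rose in 7 and fell in none (8 and 4 over the list alone, adjusted p = 0.397). The imprinted median of 0.00 was -0.03 after median centring, and Igf2 rose by 1.42 ± 0.15. Pluripotency regulators rose in 8 and fell in none, the same over the list alone (adjusted p = 0.0551, median 0.09). The reprogramming factor gene Klf4 rose by 0.98 ± 0.16. That list passed with median centring (0.0434), quantile normalization (0.0441), cyclic loess (0.023), the trend prior (0.0429) and the replicate block. It also passed without untreated control replicate 2 (0.0492) and without treated control replicate 1 (0.0333). DNA methylation factors rose in 6 and fell in 1 (7 and 1 over the list alone, adjusted p = 0.261), median 0.07, or -0.01 after quantile normalization, with the imprint-protecting pair Trim28 (1.48 ± 0.17) and Zfp57 (1.12 ± 0.16) among the rises, and passed without treated mutant replicate 1 (0.0129). Trithorax and demethylase genes had 3 rises and 4 falls (3 and 5 over the list alone, adjusted p = 0.59), a median of 0.01 (-0.02 after median centring) and a downward camera direction, with the H3K4 demethylase gene Kdm1a at 1.67 ± 0.11 and the H3K27 demethylase gene Kdm6b at -0.68 ± 0.12.

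The 2-cell activation genes had 3 rises and 2 falls, the same over the list alone (adjusted p = 0.878), a downward camera direction and a median of 0.06, or -0.00 after quantile normalization, with Arg2 at 1.11 ± 0.18. Targets of p53 had 4 rises and 1 fall (5 and 1 over the list alone, adjusted p = 0.081, median 0.09) and passed without treated control replicate 3 (0.0477) or treated mutant replicate 1 (0.0447). Ddit4 rose by 1.17 ± 0.19 and Rrm2b fell by 1.07 ± 0.15. The unfolded protein response list had 4 rises and no falls (5 and none over the list alone, adjusted p = 0.878), a median of -0.03, a mean of 0.04 and a downward camera direction. Signalling genes had 1 rise and 6 falls (1 and 7 over the list alone, adjusted p = 0.174, median -0.01). Tgfb2 fell by 1.36 ± 0.16, Fgf9 by 1.16 ± 0.15 and Bmp6 by 0.92 ± 0.13. In the CDK list Ccnd2 (1.11) and Cdkn1c (0.78) rose and none fell, the same over the list alone (adjusted p = 0.59). The latter call was lost without treated mutant replicate 2 (0.56), and the median of 0.02 changed sign under all 3 scalings. Cumulus markers had 1 rise, Ptgs2 at 1.32 ± 0.16, the same over the list alone (adjusted p = 0.852), and a median of 0.01, which was -0.02 after median centring and -0.00 after quantile normalization. No sperm marker changed by limma's test (adjusted p = 0.498, median -0.02).

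Members behind small counts here were chosen after their values were seen. Falls against the direction of their list were Srsf10 (-0.94) in splicing, Psme4 (-0.77) and Psme3 (-0.57) in the proteasome, Ect2 (-0.75), Wee2 (-0.71), Kif18a (-0.66) and Smc4 (-0.54) in mitosis, Fbl (-0.57) in ribosome biogenesis, Orc2 (-1.01), Orc5 (-0.78) and Dbf4 (-0.68) in replication, and Hsf1 (-0.63) among chaperones. Etf1 (-0.82), Eif5 (-0.76), Eif3j1 (-0.67) and Eif4g2 (-0.64) fell among translation factors, and Nlrp4e (-1.05), Gpr3 (-0.88), Cnot6l (-0.78), Cnot7 (-0.49) and Kit (-0.42) among oocyte genes. Hoxc13 (0.71) and Hoxd1 (0.46) rose among Hox genes, and Bmp7 (0.54) was the signalling gene that rose. Sp110 (1.29) rose and Nelfa (-0.68) fell in the 2-cell list, Pmaip1 and Perp rose among p53 targets, and Pdia6 rose in the unfolded protein response list. Hoxc13 and Sp110 were not called with only the groups compared.

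**Figure D2:**
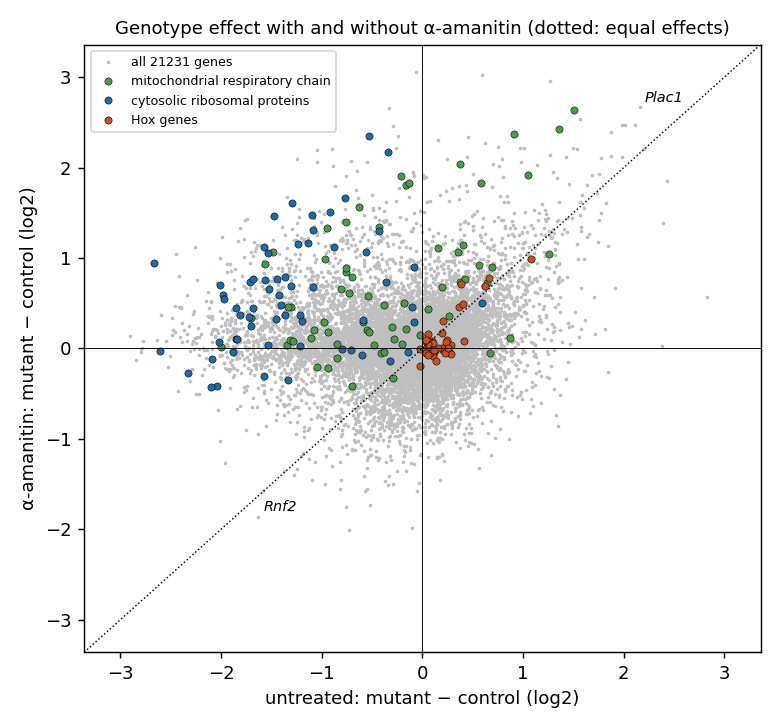
Log2 difference of mutant minus control embryos for each gene, untreated (horizontal axis) and with α-amanitin (vertical axis), with respiratory chain genes in green, ribosomal proteins in blue and Hox genes in orange. Ribosomal proteins lie mostly left of 0 and mostly above it, with medians of -1.37 untreated and 0.48 with α-amanitin, Hox genes have medians of 0.17 and 0.04, and Rnf2 lies low on both axes.

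The genotype effects with and without α-amanitin, which share no array, correlated weakly across all probe sets (Pearson 0.0592, Spearman 0.0654). Quantile normalization gave a Pearson correlation of 0.115, leaving out treated mutant replicate 1 gave -0.0047 and leaving out replicate 2 gave 0.116. Plac1, Rgs2, Tubb3 and Ddah1 rose in both, as did Kdm2b, Hoxd8, Hoxd9, En2, Sohlh2, Pabpc1l, Igf2 and Ptgs2, and Rnf2 and Suz12 fell in both. Altogether 648 probe sets rose in both, where independent lists share 130.6 (odds ratio 9.23), and 376 fell in both against 167.3 (odds ratio 2.95). A further 516 fell untreated and rose with α-amanitin, against 262.5 (odds ratio 2.48), among them Cdc45. Only 75 rose untreated and fell with α-amanitin, against 83.3. Independent lists, here and below, ignore that dim probe sets are seldom called, which may add to each excess. The number rising in both was 397 without treated mutant replicate 2 and 979 after quantile normalization, and the number falling in both was 189 without treated mutant replicate 1 and 247 without untreated control replicate 1.

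Untreated and α-amanitin-treated control embryos were compared to find RNA that depends on transcription in the embryo. Untreated embryos held more RNA for making ribosomes, splicing and degrading proteins: 68 of 70 ribosome biogenesis genes, 60 of 63 ribosomal protein genes, 52 of 59 splicing factors and 33 of 40 proteasome subunits were higher, as were 27 of 36 genes of the 2-cell activation list. Of 56 oocyte and maternal-effect genes, 37 were lower in untreated embryos and 3 higher. In all, 9473 probe sets changed, 5527 higher and 3946 lower in untreated embryos (58.3% higher), and after quantile normalization 4717 were higher and 6194 lower (43.2% higher). The untreated and treated arrays did not overlap in 13941 probe sets, where chance gives 10%.

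The predicted gene LOC674295 had the largest difference (6.66 ± 0.17), followed by Cd63, which encodes a lysosomal and exosomal membrane protein (5.92 ± 0.25, adjusted p = 1.01e-07, 60.5-fold higher, n = 3 and 3). Prps1, which makes the ribose phosphate donor of nucleotide synthesis, was higher by 5.46 ± 0.27, Impdh2, of guanine nucleotide synthesis, by 5.32 ± 0.30 and Ppat, of purine synthesis, by 5.01 ± 0.25. Selenos, of endoplasmic reticulum quality control, was at 5.26 ± 0.21, the pyridoxal kinase gene Pdxk at 5.09 ± 0.35, Alppl2, an alkaline phosphatase of early embryos, at 4.98 ± 0.31, the autophagy gene Gabarapl2 at 4.95 ± 0.27, the phosphate transporter gene Slc34a2 at 4.88 ± 0.24 and Rpl36al at 4.80 ± 0.31. Among named genes, the largest falls were those of Psenen (-2.72 ± 0.14), Pla2g4c (-2.48 ± 0.11), Stard3nl (-2.42 ± 0.13), Olfr976 (-2.27 ± 0.19), G6pdx, the first enzyme of the pentose phosphate pathway (-2.12 ± 0.14), and Wee2, an oocyte kinase that holds meiotic arrest (-2.11 ± 0.16).

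With an estimated correlation none of the 14 lists called for this comparison passed (adjusted p = 0.207 to 0.406). Ribosome biogenesis had a median of 2.04 and 69 rises over the list alone (camera adjusted p = 8.82e-38). Mybbp1a was higher by 3.68 ± 0.16. Ribosomal proteins had a median of 2.92 and 60 rises over the list alone (camera adjusted p = 2.76e-34). Rplp1 was higher by 3.67 ± 0.17 and Rps21 by 3.43 ± 0.13. Splicing factors had a median of 1.28 and 53 rises over the list alone (camera adjusted p = 5.5e-22). Sf3b5 was higher by 2.63 ± 0.11. The 2-cell activation genes had 1 fall, Zfp560 (-0.73), a median of 1.79 and the same counts over the list alone (camera adjusted p = 1.39e-14). Pramel7 was higher by 4.43 ± 0.21, Kdm5b by 4.17 ± 0.19 and Zfp352 by 3.89 ± 0.16. Respiratory chain genes were higher in 50 and lower in 2 of 66 cases (51 and 2 over the list alone), median 1.01 (adjusted p = 7.04e-16). Ndufa2 was higher by 3.57 ± 0.16. Translation factors were higher in 37 and lower in 1 of 48 cases, the same over the list alone, median 1.24 (adjusted p = 2.3e-15). Pabpc1 was higher by 3.50 ± 0.17. Proteasome subunits were lower in 2 cases (34 higher and 3 lower over the list alone), median 1.46 (adjusted p = 6.42e-14). Psmb5 was higher by 4.47 ± 0.23.

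Mitotic genes were higher in 36 and lower in 6 of 53 cases (37 and 7 over the list alone), median 1.12 (adjusted p = 1.49e-11). Cdk1, the M-phase kinase gene, was higher by 2.96 ± 0.18 and Cdc20 by 2.66 ± 0.15. Chaperones were higher in 20 and lower in 2 of 29 cases (24 and 3 over the list alone), median 1.46 (adjusted p = 1.23e-09). Hsp90ab1 was higher by 2.60 ± 0.13. Oocyte genes had 3 rises and 41 falls over the list alone and a median of -0.62 (adjusted p = 2.61e-09), with the oocyte growth factor gene Bmp15 at -1.99 ± 0.12, Obox5 at -1.83 ± 0.14 and Nlrp4e at -1.78 ± 0.13, and Dppa3 at 2.36 ± 0.12. Replication genes were higher in 28 and lower in 7 of 52 cases, the same over the list alone, median 0.39 (adjusted p = 2.96e-06). Ccne1, the cyclin gene of S-phase entry, was higher by 3.63 ± 0.16. Unfolded protein response genes were higher in 15 and lower in 2 of 27 cases (17 and 2 over the list alone), median 0.50 (adjusted p = 1.99e-05). Dnajb9 was higher by 3.68 ± 0.23. Targets of p53 were higher in 15 and lower in 2 of 33 cases (16 and 5 over the list alone), median 0.18 (adjusted p = 0.00698). Sesn2 was higher by 3.56 ± 0.16. Glycolysis genes were higher in 11 and lower in 4 of 22 cases, the same over the list alone, median 0.39 (adjusted p = 0.0138), with Ldha at 1.40 ± 0.11, and this call was lost after quantile normalization (0.127) and over the brighter 50% of probe sets (0.185), as was that of p53 targets over the brighter 50% (0.0511). After quantile normalization the medians of splicing, replication and unfolded protein response genes were 0.83, 0.18 and 0.12.

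The lists that did not pass included Hox genes, with 1 fall, Hoxa7 at -0.43 ± 0.09, the same over the list alone (adjusted p = 0.145, median -0.10), and PRC1 subunits, with 7 rises and 6 falls (8 and 7 over the list alone, adjusted p = 0.716) and a median of 0.03 that was -0.09 after quantile normalization. Pcgf5 was higher in untreated embryos by 2.66 ± 0.16 and L3mbtl2 by 1.93 ± 0.19, and Scmh1 fell by 1.37 ± 0.15. PRC2 had 3 rises and 2 falls (5 and 2 over the list alone, adjusted p = 0.451), a mean of 0.31, a median of -0.01 and an upward camera direction, with Mtf2 at 1.99 ± 0.17, Rbbp4 at 1.53 ± 0.11 and Ezh2 at 0.60, chosen after its value was seen, and Suz12 at -0.66 and Phf1 at -0.51. The Phf1 call was lost without untreated control replicate 3 (-0.48) or treated control replicate 1 (-0.41). Pluripotency regulators had 14 rises and 5 falls (14 and 7 over the list alone, adjusted p = 0.132, median 0.09). Dppa4 was higher by 2.79 ± 0.17 and Nr5a2 by 2.1 ± 0.18. The falls were Tcl1 (-1.78 ± 0.14) and, chosen after their values were seen, Pou5f1 (-1.42), Lin28a (-0.84), Yap1 (-0.64) and Lin28b (-0.34). Among markers of other cells, Amhr2 was the cumulus marker that rose (2.1 ± 0.12, list adjusted p = 0.329).

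In mutant embryos, the same treatment comparison gave fewer changes, but the 2-cell activation genes stood out: 24 of 36 were higher in untreated embryos and none lower (29 and none over the list alone), median 1.14 (camera adjusted p = 3.06e-43, 0.0316 with an estimated correlation). Zfp352, a zinc finger gene transcribed at this stage, had the largest difference after LOC674295 (5.06 ± 0.18, adjusted p = 6.1e-07, 33.3-fold higher, n = 3 and 2), and Gm4340 (4.06 ± 0.21), Tdpoz1 (3.14 ± 0.24), Tmem92 (2.33 ± 0.17) and Kdm5b (2.21 ± 0.21) were also higher. Prps1 (3.69 ± 0.31), Cd63 (3.34 ± 0.28) and Slc34a2 (3.13 ± 0.27) rose as in control embryos. In all, 1238 probe sets changed, 885 higher and 353 lower in untreated embryos (71.5% higher), and after quantile normalization 2177 changed, 1290 higher and 887 lower (59.3% higher). The count depended on single arrays: it was 1908 (631 higher and 1277 lower) without treated mutant replicate 1, 798 (726 and 72) without treated mutant replicate 2, 643 without untreated mutant replicate 1 and 792 without untreated mutant replicate 3. Array weights gave 558 and only the groups compared gave 142. The arrays did not overlap in 9202 probe sets, where chance gives 20%.

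With an estimated correlation none of the 7 lists called in this comparison other than the 2-cell genes passed (adjusted p = 0.312 to 0.929). Ribosomal proteins were higher in 26 and lower in none of 63 cases in untreated mutant embryos (42 and 1 over the list alone), median 0.73 (adjusted p = 3.83e-31). Rpl26 was higher by 1.95 ± 0.24 and Rpl9 by 1.92 ± 0.24. Ribosome biogenesis genes were higher in 13 and lower in none of 70 cases (23 and 1 over the list alone), median 0.30 (adjusted p = 1.69e-14). Nop16 was higher by 2.49 ± 0.26. Oocyte genes were lower in 12 and higher in none of 56 cases (29 and 1 over the list alone), median -0.39 (adjusted p = 1.7e-13), with Pabpc1l at -0.68 ± 0.10. The unfolded protein response list had 7 rises and no falls (10 and none over the list alone), median 0.23 (adjusted p = 7.36e-07). Dnajb9 was higher by 1.90 ± 0.26 and the chaperone gene of the endoplasmic reticulum Hspa5 by 1.42 ± 0.12. Rpl26, Rpl9, Pabpc1l and Dnajb9 were not called with only the groups compared. Chaperones had 4 rises and no falls (9 and 1 over the list alone), median 0.10 (adjusted p = 0.000118), with Hspa5, Cct6a (1.19), Hspa2 (1.02) and Hspa1a (0.92) as the rises, and this call was lost without treated mutant replicate 1 (adjusted p = 0.286). Translation factors had 4 rises and 1 fall (7 and 2 over the list alone), median 0.21 (adjusted p = 0.00487). The rises were Eif4a3 (1.76 ± 0.19, called in 2 of 3 probe sets), Pabpc1 (1.49), Eif3a (1.19) and Eif3c (1.15), the fall was Eif1b (-0.68), chosen after its value was seen, and the call was lost without treated mutant replicate 1 (0.911, median -0.04) or untreated mutant replicate 1 (0.156). PRC2 genes had 2 falls, Rbbp7 (-0.66) and Jarid2 (-0.47), and no rises (3 and 1 over the list alone), median -0.36 (adjusted p = 0.0102), and the call was lost without treated mutant replicate 2 (0.211), without untreated mutant replicate 2 (0.0689), over the brighter 50% of probe sets (0.0602) and with cyclic loess (0.0657). Without treated mutant replicates 1 and 2, the medians were 0.12 and 0.45 for ribosome biogenesis, -0.61 and -0.19 for oocyte genes and 0.03 and 0.36 for the unfolded protein response. Without replicate 2 they were 0.36 for translation and 0.39 for chaperones, whose median was 0.22 with cyclic loess, 0.21 without untreated mutant replicate 2, and 0.16 after quantile normalization or over the brighter 50% of probe sets. No Hox gene changed by limma's test (list adjusted p = 0.443). Splicing factors (adjusted p = 0.358), respiratory chain genes (0.264) and mitotic genes (0.525) had medians of -0.04, -0.08 and -0.10, which were 0.05, 0.01 and 0.01 after cyclic loess normalization. With cyclic loess the splicing (0.028), respiratory (0.0134) and glycolysis (0.011) lists passed, and after quantile normalization the respiratory (0.0202) and glycolysis (0.0346) lists. The mitotic list passed without treated mutant replicate 1 (0.0017, median -0.29), splicing without untreated mutant replicate 2 (0.0257), and p53 targets without untreated control (0.0449) or untreated mutant replicate 2 (0.0151). Without treated mutant replicate 2 the mitotic list passed with a median of 0.11 (0.0221), and the proteasome (2.45e-05), splicing (0.0015), glycolysis (0.0015), p53 (0.0084), respiratory (0.0167) and replication (0.0378) lists passed too.

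The treatment effect differed between the genotypes when the difference itself was tested, and for most genes higher in untreated embryos it was smaller in the mutant. The interaction passed for 4983 probe sets, 1205 above 0 and 3778 below (24.2% above), and after quantile normalization for 3323 above and 2848 below (53.8% above) and after cyclic loess for 2191 and 3821 (36.4% above). Across probe sets the effects in control and mutant embryos, which share no array, correlated at 0.608 (Pearson) and 0.379 (Spearman). Picking genes by their call in 1 genotype favours a larger effect in it, so both choices are given. Of 4082 genes called higher in untreated control embryos, 2761 had a smaller effect in the mutant by the interaction test and 6 a larger one (medians 0.93 in control and 0.14 in mutant). Of 549 called higher in untreated mutant embryos, 368 had a smaller effect in the mutant and 25 a larger one (medians 2.16 and 0.90). Of 2987 genes called lower in untreated control embryos, 835 had a smaller effect in the mutant and none a larger one (medians -0.62 and -0.21), while of 231 called lower in untreated mutant embryos 24 had a smaller and 41 a larger effect (medians -0.57 and -0.63). Of the genes called in control embryos, 511 higher and 147 lower ones were called the same way in the mutant. Probe sets higher in untreated embryos of both genotypes numbered 788 where independent lists share 140.7 (odds ratio 50), and those lower in both 194 against 40.1 (odds ratio 9.97).

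With an estimated correlation none of the 15 lists called for this comparison passed (adjusted p = 0.212 to 0.622). Ribosome biogenesis had 66 negative interactions of 70 and none positive (70 and none over the list alone), median -1.77 (adjusted p = 2.51e-40). Ribosomal proteins had 55 of 63 (58 over the list alone), median -2.0 (adjusted p = 7.59e-31), with Rps14 at -2.94 ± 0.23 and Rps21 at -2.90 ± 0.20. Splicing factors had 46 of 59 (57 over the list alone), median -1.15 (adjusted p = 7.53e-26), with Snrpd3 at -3.12 ± 0.20 and Magoh at -2.99 ± 0.18. For the respiratory chain (43 of 66, median -0.93), the proteasome (32 of 40 and 1 positive, median -1.51) and translation factors (33 of 48, median -1.17), camera gave adjusted p = 1.57e-17, 2.85e-17 and 8.8e-17. Adjusted over the list alone, these 3 lists had 47, 34 and 37 negative interactions. Mitotic genes had 35 negative and 2 positive interactions (36 and 3 over the list alone), median -1.20 (adjusted p = 2.31e-15), with Aurka at -3.10 ± 0.29, and replication genes 23 and 2 (25 and 2 over the list alone), median -0.52 (adjusted p = 8.2e-08), with Cdc45 at -2.74 ± 0.18. Chaperones had 16 and 2 (20 and 2 over the list alone), median -1.16 (adjusted p = 8.18e-08). Oocyte genes had 10 positive and 3 negative interactions (12 and 3 over the list alone), median 0.26 (adjusted p = 0.000847), with Tcl1 at 1.61 ± 0.21 and Bmp15 at 1.52 ± 0.19 and the negative ones Dppa3 (-2.75 ± 0.19) and, chosen after their values were seen, Zar1l and E330034G19Rik, and this call was lost without treated mutant replicate 1 (0.173, median -0.02). This median was 0.59 after quantile normalization, 0.47 without treated mutant replicate 2 and 0.16 without treated control replicate 1, and quantile normalization gave -0.77 for mitotic, -0.24 for replication and -0.74 for chaperone genes. For the 2-cell activation genes, 12 interactions were negative and 4 positive (12 and 5 over the list alone, adjusted p = 0.159), median -0.22, or 0.13 after quantile normalization, and the list passed without untreated mutant replicate 1 (0.0196). The positive ones were Gm4340 (2.27 ± 0.28) and, chosen after their values were seen, Zfp352 (1.17), Zfp353-ps (1.05) and Zfp560 (0.71). Among PRC1 genes, Pcgf5 had a negative interaction (-1.59 ± 0.23) and Scmh1 a positive one (1.23 ± 0.23).

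The untreated genotype effect and the treatment effect in control embryos share the untreated control arrays, and they correlated at -0.783 across probe sets, where simulated unchanged groups gave -0.500. The covariance was -0.253 against -0.0119 in the simulation, a difference of -0.241. Of 4752 probe sets lower in the untreated mutant, 3952 (83.2%) were higher in untreated than in treated control embryos, against 755.6 for independent lists, which leave out the shared arrays, and 0 in the simulation, which leaves out all effects. Bop1, Pno1, Psmb5 and the H3K4 demethylase gene Kdm5b lay among them. Of 2365 probe sets higher in the untreated mutant, 1321 (55.9%) were lower in untreated than in treated control embryos, against 268.5 for independent lists and 0 in the simulation, with Psenen, Tcl1 and Obox5 among them. The 3 untreated control arrays cannot be split into parts of at least 2, so part of the excess may come from the shared arrays.

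**Figure D3:**
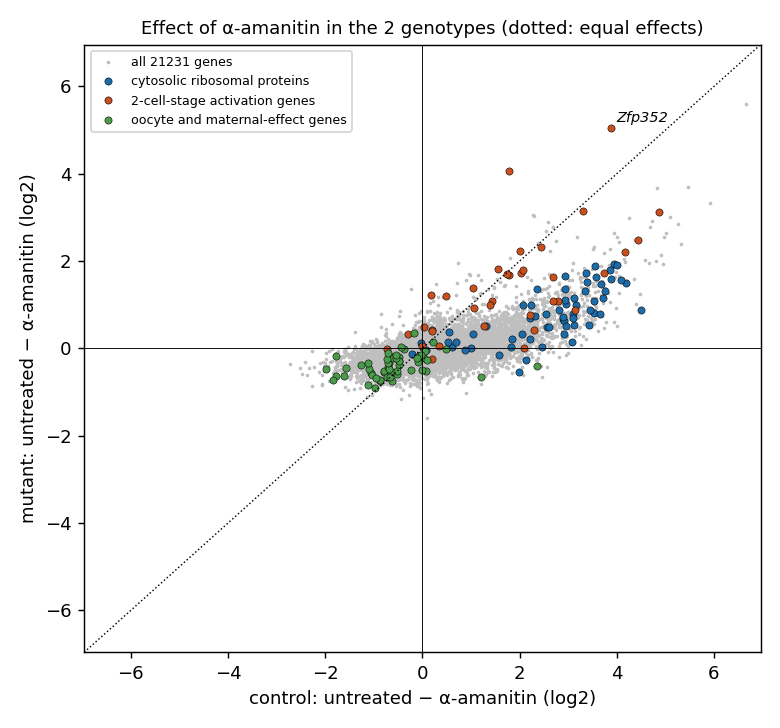
Log2 difference of untreated minus α-amanitin-treated embryos for each gene in control (horizontal axis) and mutant embryos (vertical axis), with ribosomal proteins in blue, 2-cell activation genes in orange, oocyte genes in green and equal effects along the dotted line. Most genes high in control lie below the line, ribosomal proteins with medians of 2.92 and 0.73, while Zfp352 lies at 3.89 in control and 5.06 in mutant embryos.

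**Figure D4:**
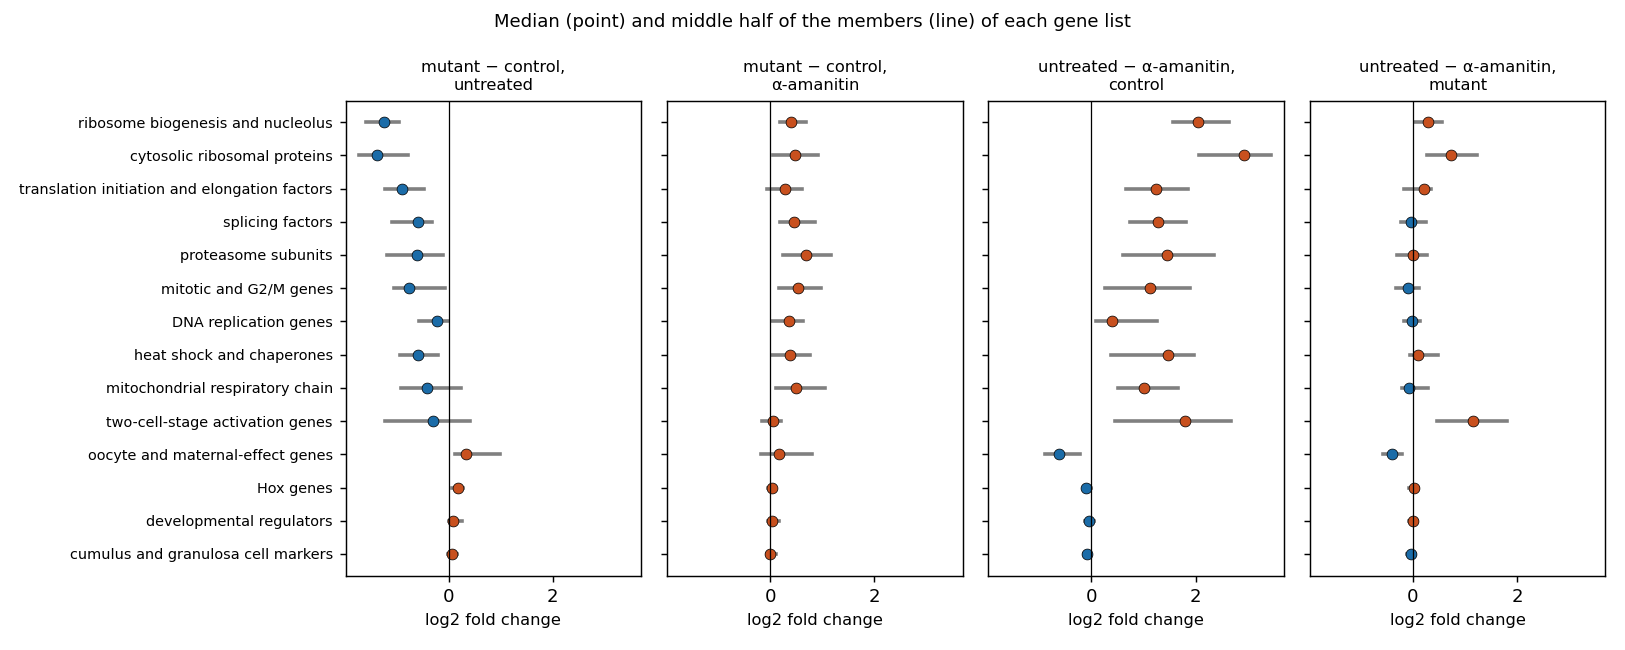
Median log2 difference (points) and middle 50% of the members (lines) for 14 gene lists in both genotype and both treatment comparisons, orange above 0 and blue below. Medians change sign after quantile normalization for 2-cell genes in both genotype comparisons (to 0.05 and -0.00), after median centring (-0.02) and quantile normalization for cumulus markers with α-amanitin, and after cyclic loess for splicing (0.05), mitotic, replication and respiratory genes (0.01 each) in mutant embryos.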

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

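The tests of an incomplete transcription block, cumulus or granulosa cells and scaling were chosen only after the results they bear on were seen. Intervals and permutation p here are over genes, not arrays.

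The results here were picked out because the genotype effect differed between untreated and α-amanitin-treated embryos by a test of the difference itself, limma's interaction. It passed for 4983 probe sets. Among gene lists, the interaction median was -1.77 for ribosome biogenesis, -2.0 for ribosomal proteins, -1.15 for splicing factors, -1.51 for proteasome subunits, -1.17 for translation factors and -0.93 for the respiratory chain. It was -1.20 for mitotic genes, -0.52 for DNA replication genes, -1.16 for chaperones, -0.26 for the unfolded protein response, -0.29 for p53 targets, -0.22 for DNA methylation factors, -0.43 for PRC2, 0.26 for oocyte genes and 0.11 for Hox genes. The largest positive interactions were those of Psenen (2.36), Stard3nl (2.1), Pla2g4c (1.89), Cdo1 (1.88) and Cntnap1 (1.86). The largest negative ones were those of Rps25 (-3.61, with 3 of 6 probe sets called), Rnf7 (-3.50), Bola2 (-3.38), Slc16a6 (-3.25) and Psma6 (-3.22). Quantile normalization ended the calls of PRC2 (adjusted p = 0.626, median 0.04), Hox genes (0.435), p53 targets (0.205), DNA methylation factors (0.697, median 0.01) and the unfolded protein response (0.437). The brighter 50% of probe sets ended those of PRC2 (0.247), Hox genes (0.153), p53 targets (0.134) and DNA methylation factors (0.338). Cyclic loess ended those of p53 targets (0.0866) and DNA methylation factors (0.0828), and the mean of a gene's probe sets the latter (0.0668). Without treated mutant replicate 2, PRC2 and Hox genes (0.0687 each), p53 targets (0.0724), DNA methylation factors (0.229) and the unfolded protein response (0.0565) lost their calls, and without replicate 1 oocyte genes (0.173). Without treated control replicate 2, PRC2, Hox genes and DNA methylation factors (0.0565 each) and p53 targets (0.0579) lost theirs, and without untreated control replicate 1 PRC2 and Hox genes (0.0635 each). DNA methylation factors also lost theirs without untreated control replicate 3 (0.0525) or untreated mutant replicate 2 (0.0745).

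The first pattern is the smaller effect of α-amanitin in mutant than in control embryos on genes higher in untreated embryos. An incomplete block in treated mutant embryos would leave some new RNA there. Of the excess of untreated mutant over treated control embryos, the treated mutant kept a median of 0.0140 for 26 genes of the 2-cell list. It kept 0.277 for 54 ribosomal proteins, a difference of -0.2631 (95% interval -0.380 to -0.159, permutation p = 0.00881). An uneven block or a genotype difference in egg RNA would give this too, so an incomplete block stays open. A compressed range of the untreated mutant arrays would lower bright genes alike, but 93 bright genes without an α-amanitin effect in control embryos had a median of -0.4207 (95% interval -0.553 to -0.277), against -1.37 for 417 genes of similar level with one. The same choice on simulated arrays without a genotype effect, which share the untreated controls, gave a gap of at most -0.0563, against -0.949 here. Compression may thus account for about -0.4207 and not for the whole. The scaling between arrays moved the share of positive interactions from 24.2% to 53.8% with quantile normalization, but the interaction median of 403 ribosomal protein, respiratory chain, ribosome biogenesis, proteasome, splicing, mitotic and replication genes went from -1.39 to -0.9729 (95% interval -1.09 to -0.866), which argues against it as the whole cause. Weaker or later genome activation in mutant embryos stays open and was not tested, as does a difference in harvest time.

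The second pattern is that ribosomal protein, respiratory chain and other housekeeping transcripts were higher in treated mutant than in treated control embryos. Cumulus or granulosa cells left in the treated mutant pools would raise their own markers too, but the 75th percentile of 30 such markers was 0.1051, against a median of 0.48 for ribosomal proteins, and Ptgs2 was the 1 marker called (4.65 to 5.96). The markers lay at 4.20 to 4.76 in treated controls, near the background, so these values exclude nothing and such cells stay open. A single deviating array is argued against by the per-array medians of 129 ribosomal protein and respiratory chain genes, which lay 0.364 above the treated control mean in replicate 1 and 0.676 above it in replicate 2, where single control arrays lay between -0.0733 and 0.0831. The size of the difference still depends on replicate 2, the array with the wider distribution. The scaling between arrays is argued against as the whole cause: quantile normalization moved the share of rises among all changed probe sets from 61.1% to 49.0%, while the median of the same 403 genes went from 0.45 to 0.4049 (95% interval 0.330 to 0.461). A different RNA content of the mutant egg is a candidate explanation that stays open and was not tested, and neither was the unstated background correction.

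The third pattern is the higher level of Hox genes and developmental regulators in untreated mutant embryos. A general rise of dim probe sets would lift random lists of the same level alike, but both medians lay at percentile 100 of 10000 random lists matched on mean level (0.17 against a central 95% of -0.03 to 0.08 for Hox genes, and 0.09 against -0.02 to 0.06 for developmental regulators), which argues against it. With α-amanitin the percentiles were 89.26 and 93.07, within the range of random lists, so a general rise of dim probe sets may account for those medians. After quantile normalization the untreated medians were 0.117 (95% interval 0.0573 to 0.191) and 0.06245 (0.0419 to 0.114), intervals that reach below 50% of the reported medians, so the scaling stays open for them. Loss of PRC1 repression is a hypothesis that these data leave open, and probe effects were not tested.

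Splits of the 6 untreated arrays into groups of 3 number 10, too few for a share under 0.05. The real split gave 7117 changed probe sets and the highest other split 0, so 1 of 10 gave as many. For gene lists the real split called 14, the highest other split 17, and 5 of 10 splits as many. For treatment in control embryos, also with 10 splits, the real split gave 9473 changed probe sets and the highest other 0 (1 of 10), and 14 called lists against 17 (4 of 10).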

How the results depend on the processing

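The setting that keeps only probe sets with a gene symbol was chosen only after the data were seen, and it gave 7015, 3310, 8863, 1441 and 5069 changed probe sets for the untreated genotype, treated genotype, control treatment, mutant treatment and interaction comparisons, all within 1.5 times of the reported counts. No probe set was called in opposite directions by the reported fit and any of the alternatives. For the mutant treatment comparison, quantile normalization gave 2177, array weights 558 and only the groups compared 142, and for the treated genotype comparison the latter 2 gave 2050 and 1231. Requiring 2-fold gave 2053, 857, 3406, 463 and 2680 in the order above, 125 probe sets higher in the mutant in both treatments and 32 lower in both, which follows from the stricter rule. An adjusted p below 0.01 gave 1504 for the treated genotype, 450 for the mutant treatment and 3054 for the interaction comparison, and 313 and 114 for both treatments, for the same reason. Quantile normalization gave 979 higher in both. The correlation of the genotype effects, 0.0592 as reported, was 0.0877 over the brighter 50% of probe sets and 0.115 after quantile normalization. Where no reason is given, the cause was not tested.

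Leaving out 1 array gave 5639 to 7649 for the untreated genotype, 2222 to 3033 for the treated genotype, 8233 to 9928 for the control treatment, 643 (without untreated mutant replicate 1) to 1908 (without treated mutant replicate 1) for the mutant treatment and 4164 to 4940 for the interaction comparison. The correlation of the genotype effects ranged from -0.0047 without treated mutant replicate 1, a change of sign, to 0.116 without replicate 2, the number higher in both from 397 (without replicate 2) to 847 (without replicate 1), and the number lower in both from 189 (without replicate 1) to 472 (without replicate 2). With 1 treated mutant array left, it was assumed to vary like the other groups. The mitotic list in the mutant treatment comparison had a median of -0.10 as reported, and from -0.29 without treated mutant replicate 1 to 0.11 without replicate 2, where it passed. Bmi1 in untreated embryos was at -0.13 without a call as reported and at 0.32 (adjusted p = 0.0407) after quantile normalization. The cause of these reversals was not tested. Of the other values of gene lists under the alternatives, 2640 stayed on their side of the threshold, among them uncalled medians that changed sign, 47 newly passed and 120 no longer passed, 62 of them with the estimated correlation. For named genes these numbers were 13522, 144 and 464.

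The replicate block gave 6886, 2727, 9277, 860 and 4603 changed probe sets, none more than 1.5 times from the reported counts. With it, the treated genotype calls of germline (adjusted p = 0.0558) and oocyte genes (0.0557) were lost. The pluripotency list passed there (0.0455). The labels do not say that a number marks a shared litter or day. Among the 3 groups of 3 arrays all 9 same-number pairs had a positive correlation of deviations (0.029 to 0.154), and in 17 of 18 comparisons an array correlated best with its own number, a hint from the data and not the design. With treated mutant arrays, whose deviations mirror each other, all 6 pairs were negative (-0.223 to -0.019) and 0 of 12 matched best. Only 3 of 15 pairs lay above 0.1, so pairing by number stays open.

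The deposited values were already log2, so another pseudocount was not applicable. Array signals near background, at log2 values of about the array medians of 4.45 to 4.55, limit how far a fall can be seen.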

Other observations

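The families here share a symbol root, and testing them was chosen only after the data were seen: 303 roots with at least 8 members were tested in each direction of 4 comparisons (2424 one-sided Fisher's exact tests, adjusted together). In untreated mutant embryos, transcripts of the RNA polymerases and of machineries that trim RNA were low. Of 28 Polr genes, which encode RNA polymerase subunits, 22 fell (median -1.09), and 19 fell after quantile normalization. Of 9 genes of the RNA exosome, which degrades and trims RNA, 8 fell (median -1.0), among them Exosc1 (-1.45), Exosc7 (-1.38) and Exosc3 (-1.36), while Exosc8 was at 0.15 without a call. Of 15 subunits of the Integrator complex, which ends transcription of small nuclear RNAs, 9 fell (median -0.63), among them Ints2 (-1.04) and Ints11 (-1.03). The same roots were higher in untreated than in treated control embryos, with 24 of 28 Polr, 8 of 9 Exosc and 11 of 15 Ints genes called, and these comparisons share the untreated control arrays. Of 12 Bmp genes, 6 rose in the untreated mutant (median 0.28), namely Bmp15 (1.12), Bmp5 (1.11), Bmp7 (0.49), Bmp4 (0.47), Bmp2 (0.38) and the kinase gene Bmp2k (0.44). Of these, only Bmp7 rose in the mutant with α-amanitin (0.54), and Bmp2k fell (-0.73). Called lower in untreated than in treated control embryos were Bmp15 (-1.99), Bmp5 (-1.58) and Bmp2k (-1.57), the others not.

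Among α-amanitin-treated embryos, 5 of 11 Cnot genes, which encode the main deadenylase that shortens poly(A) tails, were lower in the mutant (median -0.49), namely Cnot6 (-0.99), Cnot6l (-0.78), Cnot9 (-0.63), Cnot2 (-0.56) and Cnot7 (-0.49). Without treated mutant replicate 1 the count was 2, and without replicate 2 it was 6. Genes of the root Ndufa, most of them complex I subunits, rose in 9 of 15 cases (median 0.92). In untreated mutant embryos 8 of them rose and 4 fell (median 0.56), unlike the respiratory chain list, whose median fell there. Subunits of the anaphase-promoting complex rose in 5 of 9 cases with α-amanitin (median 0.53), with Anapc13 at 2.22. In control embryos, 10 of 18 Nlrp genes, a root that holds the maternal-effect gene Nlrp5 and also genes of innate immunity such as Nlrp3, were lower in untreated than in treated embryos (median -0.54), led by Nlrp4e (-1.78), Nlrp9c (-1.57) and Nlrp9a (-1.27). None of these medians changed sign with median centring, quantile or cyclic loess normalization, but some moved by over 1.5 times. Quantile normalization gave -0.66 for Exosc, -0.34 for Ints and -0.83 for Nlrp, and cyclic loess -0.31 for Cnot and -0.29 for Nlrp. The Cnot median was -0.28 without treated mutant replicate 1, and the Anapc median 0.32 without replicate 2.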
